A study of Mus musculus with 3 samples.

How the data were processed

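The series held 3 single-cell libraries. CD45 bead-selected skin cells of MC903-treated mice (control) and of mice given RHS and MC903 were captured on the BD Rhapsody microwell system. Nuclei of sympathetic ganglia (abbreviated in the labels as SCG, STG, T2-T4 and CG) were captured with the 10x Genomics 3' v3.1 chemistry. The title of the ganglia sample calls it skin, while its tissue label, its description and its neuronal transcripts say ganglia. The preparation text describes its mice as MC903-challenged and the description as given RHS and MC903; the group follows the description. The deposited matrices hold raw UMI counts per gene and barcode with no normalization, per the file headers and the whole numbers in them. Per the file headers the ganglia counts were written by Cell Ranger 7.1.0. Per the submitters' processing notes the genome build was GRCm39 and R 3.6.0, Seurat 5.1.0 and Cell Ranger were used, with no role given for each. The program that called the skin barcodes is not given in the sources used here. Every deposited barcode held at least 500 UMIs.

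The skin libraries listed 31253 genes and the ganglia library 32285. Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept in skin, and nuclei with at least 200 genes and at most 5% in the ganglia. This removed 54, 92 and 1 barcodes for few genes and 246, 237 and 197 for mitochondrial UMIs in the control, RHS and ganglia libraries. Doublets were scored per library with Scrublet as run by scanpy 1.11.5 at an expected share of 6%, and 146 (1.15%), 115 (0.880%) and 2 (0.0440%) were removed. The low numbers leave undetected doublets in the classes, and in the ganglia library the score separated almost none. Median mitochondrial shares of kept cells were 4.75%, 4.68% and 0.211%. Counts were scaled to 10000 UMIs per cell and log1p-transformed. The 2000 most variable genes entered 30 principal components, with 15 neighbours and Leiden clustering at resolution 1.0. The skin libraries were clustered together without integration, and noradrenergic nuclei were sub-clustered at resolution 0.5. The other tools were anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, umap-learn 0.5.12, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9 and Python 3.11.15.

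Clusters were named from 26 skin and 19 ganglia marker classes. The markers, gene lists, filters, resolutions, comparisons and the rule for naming genes were fixed before the data were examined; the rule for naming clusters was set after seeing the data. A marker counted as present with a UMI in at least 5% of a cluster's cells and a level over 2 times the mean of the other clusters. The class was the one with the highest mean log2 ratio of marker CPM over other clusters, with 10 CPM added to both, and a joint name was given to classes within 0.25 of each other, if the second class also had at least 3 markers present and was not the erythroid class. A cluster stayed unnamed with fewer than 3 markers, with more markers of other classes than its own among its top 10 genes, or when shallow with no own marker there. Added checks left clusters with neuronal or central myelin genes, or without Th and Dbh, out of the named ganglia classes. During this work a minimum score was dropped and a rule on Dbh alone was widened to Th or Dbh. This left 6 skin and 5 ganglia clusters unnamed.

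Shares of cells were given with exact Clopper-Pearson 95% intervals, and their ratios with intervals conditional on the counts. Expression was compared for classes with at least 50 cells in each skin library. Counts were summed per class and library and expressed as CPM with exact Poisson intervals, and ratios of RHS over control had exact conditional binomial 95% intervals. A gene with 0 counts in a library was set at a floor of 3 counts and given as a bound. Cells are not replicates, so no test between groups was run and no p-value is given. The class totals ranged from 52573 UMIs (the Prg2 and Ccr3 cluster, control) to 10528671 (macrophage-like, RHS), which sets the width of the intervals. Shares of nuclei with a UMI were also computed after thinning to 900 UMIs, the lower quartile of the Schwann cell-like nuclei rounded down.

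Genes were named by a fixed rule. In the eosinophil class up to 12 genes with the highest and 12 with the lowest ratio, and in the 6 other classes with most cells 3 of each, were named. They needed at least 50 counts in the higher library and a ratio of at least 1.5 either way, and a higher gene needed at least the level of all other cells. Mitochondrial, ribosomal, haemoglobin, antigen receptor, sex-linked and predicted genes were left out of naming. From each list the 2 highest and 2 lowest members with at least 20 counts were named, and in the ganglia the 4 members with the highest CPM. Siglecf, Ccr3, Il5ra, Epx, Prg2, Il4, Il13 and Ccl11 in skin, and Th, Dbh, Npy, Pdyn and Ccl11 in ganglia, were always given. Some genes that these rules pick are not reported here. The 16 skin lists covered type 2 cytokines, chemokines, eosinophil genes, adrenergic, opioid and neuropeptide receptors, cAMP and glucocorticoid responses, lipid mediators, inflammatory cytokines, interferon response, immediate early genes, antigen presentation, glycolysis, survival, proliferation, Fc receptors and oxidative phosphorylation. Each list's median log2 ratio was set against 10000 random lists matched on expression in 20 bins. The 9 ganglia lists covered catecholamine genes, neuropeptides, chemokines and cytokines, their receptors, stress hormone, nicotinic and adrenergic receptors, neurotrophins, cholinergic, immediate early and opioid genes. Listed symbols absent from the files (Mx1 and Icer among them) were not measured.

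The intervals were tested on simulated data by Poisson draws from the mean profile of 3 classes at their real depths, with 200 changed genes. The draws follow the counting model that the intervals assume, with genes independent and no variation between cells, mice or libraries. They therefore check counting error only. Of 100 genes with a fold of 2, 64 in the Prg2 and Ccr3 cluster, 86 in alpha-beta T cell-like and 84 in macrophage-like cells had an interval on the right side of 1, and of 100 with a fold of 4, 93, 94 and 97. Of unchanged genes 3.63%, 4.12% and 4.33% had an interval without 1, and of 200 unchanged lists 4%, 3.5% and 7% lay outside the central 95%. Alternatives tried were 500 genes per cell (1000 in ganglia), 10% mitochondrial UMIs (1% in ganglia), doublets kept, resolutions of 0.5 and 2.0, separate clustering, a marker gate for eosinophils, shares without neutrophils, scaling by the median ratio, subtraction of a 5% free-RNA share and higher count minimums. Clustering without the fixed markers, shares among clusters with Ptprc, ratios relative to the other classes and the row named Nrp2 in place of Pdyn were added after seeing the data. Subtracting free RNA gave no ratio where both libraries were left with 3 counts or fewer. No genome coordinates were used, since the annotation at hand was of build GRCm38. Raw reads were not analysed here.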

Results

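Single-cell and single-nucleus RNA counts were collected from mice with skin inflammation raised by MC903 (calcipotriol, a vitamin D analogue that gives atopic dermatitis-like lesions). The series concerns a sympathetic nerve and eosinophil axis by which stress worsens skin inflammation. The 3 libraries formed 3 groups of 1 library each. The skin control library held CD45 bead-selected cells of MC903-treated mice, and the skin RHS library held such cells of mice given RHS as well as MC903; the labels do not expand RHS. The ganglia library held nuclei of sympathetic ganglia of mice given RHS and MC903, pooled from 30 mice, and had no partner group. The number of mice behind each skin library is not given in the sources used here. The deposited counts held 12979 barcodes with 55200784 UMIs (skin control), 13339 with 52762576 UMIs (skin RHS) and 4706 with 11101393 UMIs (ganglia). No deposited barcode had fewer than 500 UMIs. The filters kept 12577, 12953 and 4507 cells or nuclei, with medians of 3233, 3101 and 1542 UMIs. With 1 library per group there was no replicate check, so every interval below is a 95% interval that covers counting error only. Classes are called "like" because they rest on marker genes.

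The first comparison asked which skin cells differed in share between the RHS and the control library. In the RHS library, alpha-beta T cell-like and macrophage-like cells each took a larger share than in the control library, while gamma-delta T cell-like, keratinocyte-like, melanocyte-like and mast cell-like cells took a lower share. Alpha-beta T cell-like cells, which carry the common T cell receptor, were 6.28% of captured cells in the control library (790 cells, 5.86 to 6.72%) and 15.2% in the RHS library (1973 cells, 14.6 to 15.9%), a ratio of 2.43 (2.23 to 2.64). This ratio depended on the clustering, at 1.31 with each library clustered separately and from 1.65 to 1.76 under 3 other settings. The class joined cluster 4, with Gzma and Cd8a among its leading genes (380 and 1160 cells, 2.96), and cluster 6 (410 and 813 cells, 1.93). Macrophage-like cells were 7.20% (905 cells) and 14.3% (1848 cells), a ratio of 1.98 (1.83 to 2.15). Most of them lay in cluster 1 (715 and 1464 cells), with 171 and 329 in cluster 17 and 19 and 55 in cluster 28. Monocyte-like cells, from which macrophages can arise, were 6.27% and 8.11%, a ratio of 1.29 (1.18 to 1.42). Gamma-delta T cell-like cells, a main source of interleukin 17 in mouse skin, were 6.77% (851 cells) and 2.52% (327 cells), a ratio of 0.373 (0.327 to 0.424).

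Among cells that CD45 selection should remove, keratinocyte-like cells were 11.2% (1406 cells) and 5.38% (697 cells), a ratio of 0.481 (0.439 to 0.527). Cluster 14 held 557 of them in the control library and 77 in the RHS library, against 650 and 420 in cluster 10 and 199 and 200 in cluster 20. Melanocyte-like cells gave a ratio of 0.328 (0.237 to 0.447) and mural cell-like cells 1.64 (1.31 to 2.06). Fibroblast-like cells were 66 and 172 cells, a ratio of 2.53 (1.89 to 3.41), which turned to 0.583 when clustering left out the fixed marker genes, a setting chosen after seeing the data. Cluster 19, left unnamed although it carried 6 fibroblast markers, held 316 and 90 cells, a ratio of 0.277 (0.216 to 0.351), so no direction is given for all fibroblast lineage cells. The bead selection, the 500-UMI minimum and the carry-over of non-immune cells can each set these shares. Cells in clusters with at least 100 CPM of Ptprc, the gene of CD45, were 65.9% (65.0 to 66.7%) of the control and 76.5% (75.7 to 77.2%) of the RHS library.

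Mast cell-like cells, a source of histamine, were 1.70% (214 cells) and 0.980% (127 cells), a ratio of 0.576 (0.459 to 0.721). Migratory dendritic cell-like cells gave a ratio of 0.691 (0.585 to 0.816) and basophil-like cells 0.830 (0.716 to 0.961). Dendritic cell-like cells of type 2 (cDC2) were 11.2% and 11.6%, and Langerhans cell-like cells, the dendritic cells of the epidermis, were 5.02% and 4.99%. The ratios of those 2 classes and of the dendritic type 1 (cDC1), NK, neutrophil, regulatory T, endothelial and Schwann cell-like classes had intervals that included 1. The cDC2-like class joined clusters that went opposite ways. Cluster 2 held 848 and 1030 cells (1.18, 1.08 to 1.29) and cluster 11 held 559 and 467 (0.811, 0.716 to 0.919). The cDC2-like ratio was 0.877 at resolution 0.5 and 0.794 at resolution 2.0. Gene ratios of this class below are to be read with this make-up. Of the 6 unnamed clusters, cluster 0 was 13.4% and 10.1%, with median depths of only 1391 and 1012 UMIs, and cluster 7 was 5.22% and 4.11%. Cluster 26 is described with the eosinophils. Cluster 29 had 51 and 16 cells and cluster 30 had 2 and 14.

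**Figure D1:**
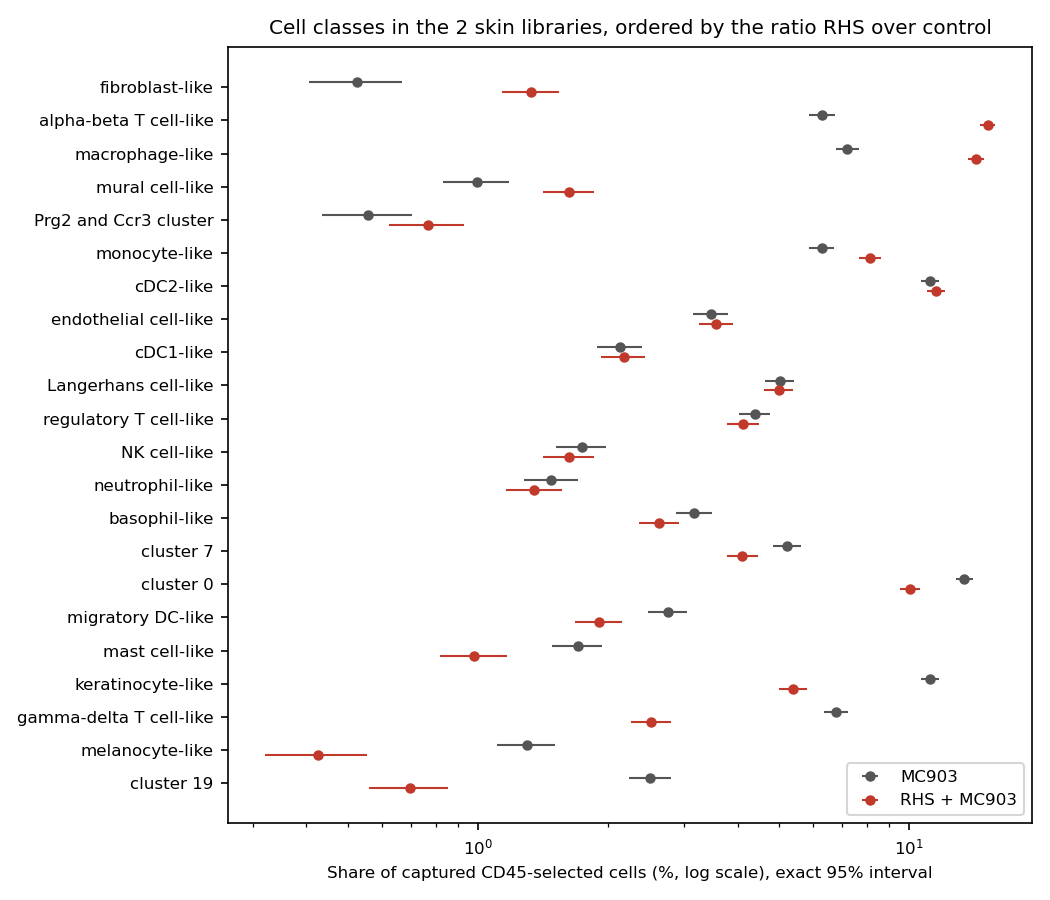
Share of captured CD45-selected cells (percent, log scale, horizontal axis) of each class (vertical axis) in the skin control and skin RHS libraries, with exact 95% Clopper-Pearson intervals as bars. Alpha-beta T cell-like cells sit at 6.28% and 15.2%, and gamma-delta T cell-like cells at 6.77% and 2.52%.

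The second comparison concerned eosinophils, which the series title names. The skin held few cells with eosinophil transcripts in either library, and the direction of the difference in their share depended on the cell filter. The cells nearest to eosinophils formed cluster 26, which showed Prg2 (ENSMUSG00000027073), a granule protein gene, and Ccr3 (ENSMUSG00000035448), the eotaxin receptor gene. With 2 of the 9 fixed markers it fell short of the naming rule, so it is called the Prg2 and Ccr3 cluster. It held 70 of 12577 control cells (0.557%, 0.434 to 0.703%) and 99 of 12953 RHS cells (0.764%, 0.622 to 0.930%), a ratio of 1.37 (1.00 to 1.89). Its cells had medians of 644 and 627 UMIs, close to the 500-UMI minimum, so eosinophils under that minimum are missing from both shares. Where at least 500 genes per cell were required, the corresponding cluster was named eosinophil and held 28 and 26 cells, a ratio of 0.910. Epx, the eosinophil peroxidase gene, had 1 UMI in the control library and 0 in the RHS library over all cells. Over all cells Siglecf was at 0.896 and 1.65 CPM, Il5ra at 0.429 and 0.310 CPM, Ccr3 at 4.80 and 5.74 CPM and Prg2 at 1.61 and 1.24 CPM. Cells with UMIs of at least 2 of the 9 eosinophil markers were 5.52% and 7.18%, but 68.0% of them were cDC2-like and 13 of 1624 were in cluster 26.

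Within cluster 26 the genes with the lowest and highest ratios are given by the fixed rule, and several turned direction with a filter of 500 genes per cell, as given below. Slpi, a leukocyte protease inhibitor, had 65 counts in the control and 7 in the RHS library, 12.1-fold lower (ratio 0.0827, 0.0320 to 0.180). Ptgs2, the inducible cyclooxygenase, had 53 and 24 counts, a ratio of 0.348 (0.205 to 0.573). The chemokine genes Ccl3 and Ccl4 had ratios of 0.475 (0.350 to 0.641) and 0.505 (0.346 to 0.731). Clec4e, a receptor for microbial glycolipids, was at 0.261 and St3gal4 at 0.307. Also lower were Zfp36, which speeds cytokine mRNA decay (0.502), the survival gene Mcl1 (0.560), Klf6 (0.583), Hmox1 (0.621), Peg10 (0.642) and S100a6 (0.651). Abca1, which exports cholesterol, had 13 and 50 counts, a ratio of 2.95 (1.58 to 5.93), and was the gene with the highest ratio among the 10 higher candidates. Serpinb2 was at 1.56 (1.17 to 2.08), Nfkb1 at 1.78 (1.18 to 2.75), Rgs2 at 1.61 (1.14 to 2.29), Mctp1 at 1.79, Cdc42 at 1.77, Cnbp at 1.71 and Hnrnpc at 1.52. Cytip (1.60, 0.973 to 2.69) and Gadd45a (1.59, 0.981 to 2.65) had intervals that reached 1. Prg2 was lower, with 40 and 21 counts (0.403, 0.226 to 0.700), and Ccr3 was at 0.921 (0.552 to 1.55).

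Of the fixed lists in cluster 26, the cAMP-responsive list was the highest, with 5 of 7 measured members higher and a median log2 ratio of 0.34, at percentile 98.5 of 10000 random lists of like expression. Such percentiles are a description of these libraries. Its named members were Crem (8 and 23 counts, ratio 2.21, 0.953 to 5.71), Rgs2, Pde4b (0.711, 0.396 to 1.27) and Ppp1r15a (0.592, 0.375 to 0.928). The glucocorticoid-responsive list had a median of -0.71 over 4 members (percentile 3.12), with the metallothionein gene Mt2 at 0.192 (0.0563 to 0.527), a gene lower in all 19 compared classes (0.312 in the others), and the NF-kB inhibitor gene Nfkbia at 0.524 (0.312 to 0.869). None of the 4 measured inflammatory cytokines was higher (median -0.36, percentile 6.10), and Csf1 was at 0.267 (0.103 to 0.618). The immediate early list was at -0.32 (percentile 3.93). The glucocorticoid-responsive, inflammatory cytokine and immediate early lists thus lay inside the central 95% of random lists. The lists of chemokines (-0.12, with Ccl6 at 1.29, 1.12 to 1.496, but 1.605 in the other classes), type 2 cytokines (-0.14), eosinophil genes (-0.12), lipid mediators (-0.005), antigen presentation (-0.07), glycolysis (-0.38), survival (-0.26), Fc receptors (-0.11) and oxidative phosphorylation (0.10) lay inside the central 95% of random lists. Interferon genes had 1 measured member, and proliferation genes and the adrenergic, opioid and neuropeptide receptors had 0. The 52573 and 68474 UMIs of this cluster make it the least deeply measured class, and requiring 500 genes per cell turned the direction of Ccl3, Ccl4, Csf1, Peg10 and Rgs2 and gave an inflammatory cytokine median of 1.00.

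The third comparison asked how expression differed within the larger skin classes. The genes of 2 eotaxins, which attract eosinophils, went both ways between classes. Ccl24, encoding eotaxin 2, was the most elevated named gene of Langerhans cell-like cells, with 189 counts (43.3 CPM) in the control and 818 counts (187 CPM) in the RHS library, a ratio of 4.32 (3.68 to 5.09). In cDC2-like cells Ccl24 had 53 and 140 counts (2.53, 1.83 to 3.54), a direction that turned with doublets kept and with 500 genes per cell. In migratory dendritic cell-like cells Ccl24 was lower (47 and 6 counts, 0.19992, 0.0698 to 0.469). Ccl11, encoding eotaxin 1, was at 226 and 320 CPM in fibroblast-like cells (1.41, 1.08 to 1.87) and at 93.8 and 181 CPM in mural cell-like cells (1.93, 1.32 to 2.87). In endothelial cell-like cells Ccl11 was at 0.790 (0.488 to 1.27), and in keratinocyte-like cells it had 15 and 1 counts (0.144, 0.00343 to 0.938). Fibroblast-like cells had a median ratio over all genes of 0.11 on the log2 scale, and melanocyte-like cells and cluster 19 of -0.144 and -0.185, against which their values are to be read.

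Macrophage-like and monocyte-like cells had lower transcripts of the interferon response, the antiviral genes induced by interferons, in the RHS library. In macrophage-like cells 16 of 17 measured members were lower, with a median log2 ratio of -0.83 (percentile 0 of the random lists). In monocyte-like cells 14 of 15 were lower, with a median of -0.80 (percentile 0). Irf7, a transcription factor that amplifies the response, was at 0.289 (0.211 to 0.395) and 0.227 (0.135 to 0.369). Ifi44 was at 0.414 in macrophage-like cells and Ifit2 at 0.236 in monocyte-like cells. Cxcl9 was at 1.03 and 1.38. Outside the list, Oas1g (59 and 22 counts, 0.191, 0.112 to 0.317) and Oas1a (315 and 145 counts, 0.236, 0.193 to 0.288), both RNA sensors induced by interferon, were among the 3 lowest named genes of macrophage-like cells. Both were lower in other classes too, with medians there of 0.262 for Oas1g, inside its interval, and 0.412 for Oas1a. For Irf7 the median of the classes other than monocyte-like cells was 0.438. The list was also lower in mast cell-like cells (median -0.89, 7 of 8 lower, Ifit1 57 and 1 counts, 0.0313, 0.000779 to 0.181), gamma-delta T cell-like cells (-0.635) and Langerhans cell-like cells (-0.37, but -0.07 relative to the other classes). It was not apart from random lists in cDC2-like (-0.11), alpha-beta T cell-like (-0.17) and keratinocyte-like cells (-0.31). Part of the shift was common to other classes, as the medians of macrophage-like and monocyte-like cells were -0.47 and -0.38 relative to the median ratio of the other classes, a setting chosen after the data were seen.

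**Figure D2:**
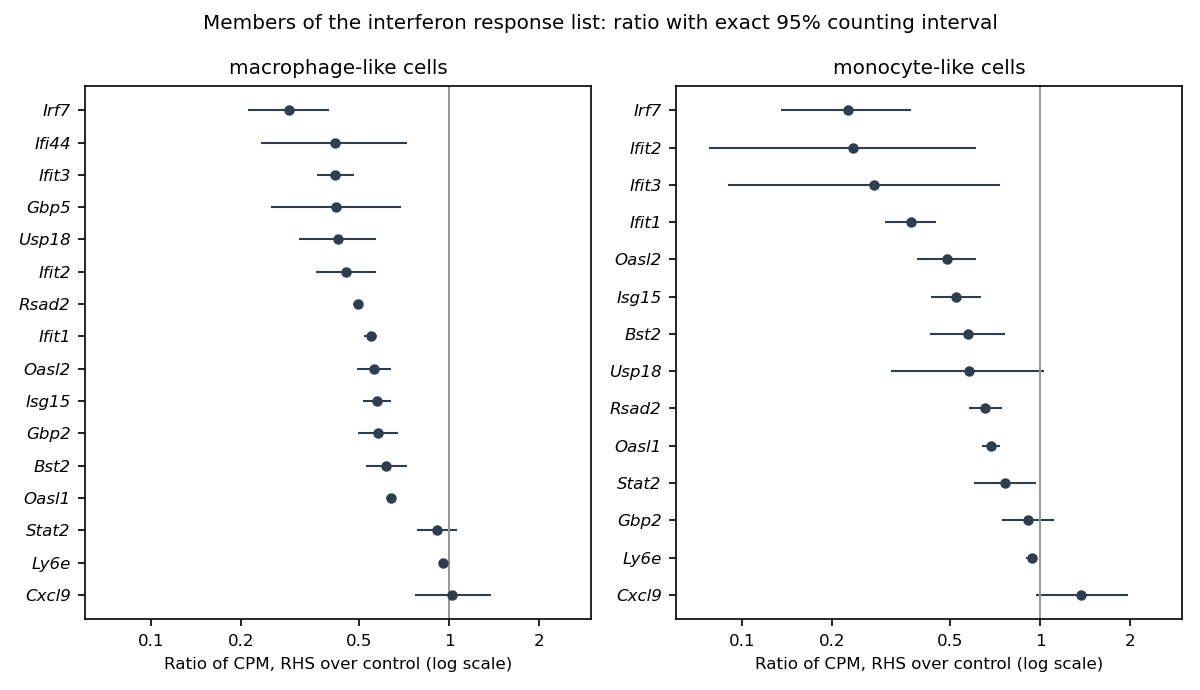
Ratio of CPM, RHS over control (log scale, horizontal axis), of measured members of the interferon response list (vertical axis) in macrophage-like and monocyte-like cells, with exact 95% counting intervals as bars and a line at 1. Irf7 is the lowest member in both panels, at 0.289 and 0.227, and Cxcl9 is above 1 in both.

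In macrophage-like cells the lectin genes Cd209g (15 and 144 counts, 4.92, 2.89 to 9.03) and Cd209f (115 and 600 counts, 2.68, 2.19 to 3.30) had the highest ratios of the named genes. Cluster 28, which Cd209f helps to define, had 19 of 905 control and 55 of 1848 RHS macrophage-like cells. The scavenger receptor gene Cd163, on the glucocorticoid-responsive list, was at 1.66 (1.55 to 1.78), while that list's median was -0.105 and turned to 0.045 relative to the other classes. In the antigen presentation list 13 of 14 members were lower (median -0.14, percentile 0.340). Its member H2-DMa was at 0.481, but it was lower in all 10 classes that measured it and turned to a log2 ratio of 0.056 in macrophage-like cells relative to the others. Type 2 cytokine receptors were lower in macrophage-like (median -0.365) and monocyte-like cells (-0.39). Their members included Il4ra, the receptor for interleukins 4 and 13, at 0.649 (0.599 to 0.704) and 0.532 (0.470 to 0.602), but Il4ra was lower in other classes too, and relative to them it turned to a log2 ratio of 0.19 in macrophage-like cells. The survival list in macrophage-like cells was at -0.18 (percentile 0.520), with Bbc3 at 0.513. In monocyte-like cells Rnase2a, an eosinophil-associated ribonuclease gene, had 1 and 50 counts (39.3, 6.73 to 1581). Fam189a1 had 3 and 53 counts (13.9, 4.50 to 69.4) and Serpinb2 387 and 1378 (2.80, 2.4954 to 3.14).

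Monocyte-like cells also had Edn1, encoding the vasoconstrictor and itch mediator endothelin 1, 9.95-fold lower in the RHS library (125 and 16 counts, 0.1005, 0.0557 to 0.170). Their proliferation list was higher, with 11 of 12 members higher (median 0.46, percentile 99.95) and Ccnb1 at 3 and 22 counts (5.76, 1.73 to 30.0). Their glycolysis list was lower (-0.19, percentile 0.180), with Eno1 at 0.542 and Tpi1 at 1.12, and at -0.017 relative to the other classes, where Tpi1 turned. Their glucocorticoid list was at -0.18 (percentile 0.790), and at -0.039 relative to the other classes.

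In the lymphocyte classes, Gzmf, encoding the cytotoxic granule protease granzyme F, had 1 count in control and 108 counts in RHS alpha-beta T cell-like cells (49.3, 8.66 to 1965). Tmsb15b1 was also higher (2.49, 1.37 to 4.91). How many cells held the Gzmf counts is not given here. Cluster 4, with Gzma and Cd8a among its leading genes, held 380 control and 1160 RHS cells of the class, and cluster 6 held 410 and 813. Gene ratios and list medians of alpha-beta T cell-like cells are to be read with this make-up. In gamma-delta T cell-like cells the inflammatory cytokine list had a median of 0.37 (5 of 8 higher, percentile 99.72), which turned to -0.35 with at least 100 counts, -0.18 after subtraction of free RNA and -0.029 at 500 genes per cell. Il17f had 2435 and 561 counts there (0.680, 0.619 to 0.746), the chemokine receptor gene Ccr2 was at 0.701 (0.638 to 0.770), and 0 of 6 proliferation genes were higher (median -0.69). Cluster 7 was unnamed because its 10 leading genes held 2 markers of type 2 innate lymphoid cells (ILC2), Il5 and Gata3, and 1 of its best class, alpha-beta T cells. The ILC2 and alpha-beta T cell scores were 2.13 and 2.14, so the cluster may mix both. Whether its mix of cells differed between the libraries was not tested. Cluster 7 had more Il5, the main growth factor of eosinophils, per UMI in the RHS library. Il5 had 631 and 793 counts (1.82, 1.64 to 2.03), and Il1rl1, the interleukin 33 receptor gene, was at 1.71 (1.53 to 1.92). In the same cluster Il4 was at 0.477 (0.339 to 0.661), Il13 at 0.661 (0.511 to 0.849), Ifng had 219 and 4 counts (0.0265, 0.00715 to 0.0688) and Il17a 34 and 2 (0.0853, 0.00993 to 0.333). Hdc, which makes histamine, was at 2.30 (2.03 to 2.61) there.

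In basophil-like cells Il4, the cytokine that drives type 2 immunity, was at 4042 CPM (2933 counts) in the control and 5732 CPM (3431 counts) in the RHS library, a ratio of 1.42 (1.35 to 1.49). Il13 was at 1.06 (0.909 to 1.24) there. Of 10 inflammatory cytokines in these cells 9 were higher (median 0.36, percentile 99.98), with Lif at 2.10 (1.83 to 2.42) and Il1a at 0.482 (0.324 to 0.706). In mast cell-like cells Il4 was at 1.07 (0.832 to 1.37) and Il13 at 1.04 (0.844 to 1.29). The list of adrenergic, opioid and neuropeptide receptors had at most 5 measured members in any class and was inside the central 95% of random lists in all 9 classes where it had at least 3.

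The named genes of keratinocyte-like cells are to be read with the make-up of the class, cluster 14 holding 557 control but 77 RHS cells of the class. Flg, encoding the barrier protein filaggrin, had 15 and 78 counts (11.3, 6.42 to 21.1), and Serpina3j had 154 and 330 (4.64, 3.82 to 5.65). Ccn2 was at 4.04, but at 3.12 in the other classes. Hsd11b2, whose enzyme inactivates corticosterone, had 675 and 10 counts, 31.2-fold lower (0.0321, 0.0153 to 0.0593). Fzd10, a Wnt receptor gene, had 286 and 9 counts (0.0681, 0.0308 to 0.131), and Phactr1 had 76 and 0, at least 11.7-fold lower at a floor of 3 counts. Of 12 proliferation genes 11 were lower (median -0.89, percentile 0), with Ccnb2 at 0.330 (0.233 to 0.458) and Mcm5 at 0.446 (0.385 to 0.516). Of 13 antigen presentation genes 10 were higher (median 0.54, percentile 99.98), with H2-Ab1 at 1.61 and B2m at 1.59. The glucocorticoid list was at -0.305, with Mt2 at 0.201 (0.312 in the other classes), Tsc22d3 at 1.84 and Fkbp5 at 1.70. Ear2 led the eosinophil list (median 0.66, 4 of 4 higher) at 1.94 (1.39 to 2.72), about its median of 1.95 in the other classes.

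In cDC2-like cells Aldh1a2, which makes retinoic acid, had 126 and 366 counts (2.79, 2.27 to 3.44), Slc39a12 was at 2.73 (1.59 to 4.87) and Hormad1 at 2.70 (1.64 to 4.62). Hormad1 was lower in Langerhans cell-like cells (53 and 11 counts, 0.207, 0.0975 to 0.401), whose stefin-like protease inhibitor genes Stfa3 (3.25, 2.09 to 5.21) and Cstdc5 (2.66, 1.73 to 4.19) were higher. Chemokine genes were higher in cDC2-like cells (16 of 19, median 0.51), alpha-beta T cell-like cells (15 of 18, 0.60), keratinocyte-like cells (11 of 18, 0.53), monocyte-like cells (11 of 20, 0.18) and Langerhans cell-like cells (12 of 20, 0.15), all above percentile 99.5. The macrophage-like median was -0.05. Cxcl1, a neutrophil attractant, was at 1.90 in cDC2-like cells, Cxcl2 at 2.99 in alpha-beta T cell-like cells, Ccl7 at 3.81 in keratinocyte-like cells and Ccl17 at 3.04 in monocyte-like cells. Genes of other cells moved with this list in alpha-beta T cell-like cells, where the dendritic cell genes Cd74 (2.30) and H2-Ab1 (2.18) and the Fc receptor gene Fcgr2b (2.47) were higher. After subtraction of a 5% share of free RNA, the chemokine medians were 0.07 in alpha-beta T cell-like, -0.36 in keratinocyte-like and 0.002 in monocyte-like cells. Relative to the other classes, the medians of Langerhans cell-like and monocyte-like cells turned to -0.177 and -0.196, and at 500 genes per cell they were 0.011 and 0.072.

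The cAMP-responsive list was lower in Langerhans cell-like (-0.22, percentile 0.0500) and cDC2-like cells (-0.19, percentile 0.210, but -0.067 at 500 genes per cell), with Ppp1r15a at 0.529 and 0.618, and higher in alpha-beta T cell-like cells (0.155), with Nr4a2 at 1.94. Glucocorticoid-responsive genes were lower in cDC2-like (-0.20) and Langerhans cell-like cells (-0.17), with Mt2 at 0.310 and 0.306, its level in the other classes too (0.312). The immediate early and heat shock list, which can follow tissue digestion, was higher in Langerhans cell-like cells (0.29, percentile 100, but 0.095 relative to the other classes, Hspa1a at 1.52, Atf3 at 1.49, Fosb at 0.530) and lower in alpha-beta T cell-like cells (-0.19). Proliferation genes were higher in cDC2-like (0.21) and Langerhans cell-like cells (0.20) and lower in alpha-beta T cell-like cells (-0.30). In alpha-beta T cell-like cells the lists of antigen presentation (0.16), lipid mediators (0.29) and Fc receptors (0.21) were above percentile 99, and oxidative phosphorylation (-0.11) and type 2 cytokines (-0.40) were under percentile 2.5. The type 2 median turned to 0.42 with at least 100 counts and to 0.45 relative to the other classes. The type 2 list was at -0.24 in cDC2-like cells, with Il33 at 1.73 and Il4ra at 0.530, and the eosinophil list there at 0.18, but at 0 relative to the other classes, where Ear2 turned to a log2 ratio of -0.57. Fc receptor genes were at 0.31 in keratinocyte-like cells, which turned to -0.57 after subtraction of free RNA.

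Several of the lowest named genes were lower by about the same factor in many classes. Mpnd (0.194) and Lamtor2 (0.24985) in cDC2-like cells stood beside medians of 0.204 and 0.254 in the other classes. Ppp1ca, a protein phosphatase gene, was at 0.215 in alpha-beta T cell-like and 0.257 in Langerhans cell-like cells, against 0.224 and 0.223 in the other classes. Cnn2 in alpha-beta T cell-like cells was at 0.291 against 0.327. Pstpip1 was at 0.259 in cDC2-like and 0.232 in alpha-beta T cell-like cells against 0.310. Ciz1 in Langerhans cell-like cells was further from the other classes, at 0.268 against 0.511.

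The ganglia library was described for its cells and for the transcripts by which sympathetic neurons could signal to immune cells. Noradrenergic neurons were a small part of it, and they carried catecholamine genes, Npy and Gal, and the muscarinic receptor gene Chrm2. No measured chemokine or cytokine gene was higher in them than in all other nuclei beyond counting error. Noradrenergic neuron-like nuclei were 108 of 4507 (2.40%, 1.97 to 2.89%), with a median of 10793 UMIs. Adipocyte-like nuclei were 29.5%, fibroblast-like 15.3%, endothelial 13.002%, macrophage-like 12.3%, non-myelinating Schwann cell-like 5.48% (247 nuclei), lymphocyte-like 3.75% and skeletal muscle-like 3.11%. Mural (1.80%), lymphatic endothelial (1.46%), perineurial (1.20%), neutrophil (0.688%) and epithelial-like nuclei (0.422%) made up smaller classes. Unnamed clusters 6, 12, 20, 22 and 23 were 5.64%, 2.71%, 0.599%, 0.355% and 0.311%, and cluster 12, with 122 nuclei and a median of 2.79% mitochondrial UMIs, was led by haemoglobin genes (Hbb-bs at 4704 CPM) beside neuronal genes. Its Th was at 201 CPM, and its Dbh (553 CPM), Npy (1048 CPM) and Slc6a2 (957 CPM) were above those of the named neurons. Its nuclei count among the other nuclei in the ratios below. The 500-UMI minimum, the dissection and the loss of nuclei can set these shares, and the share of neurons was 4.95% with at least 1000 genes per nucleus.

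In noradrenergic neuron-like nuclei 9 of 10 measured catecholamine genes were higher than in all other nuclei beyond counting error. Th, Dbh, Slc6a2, Slc18a2 and Ddc on this list were also markers by which these nuclei were named, so their higher levels follow from the naming. The noradrenaline transporter gene Slc6a2 was at 690 CPM (650 to 733), 3.59 times the level of other nuclei (3.33 to 3.88), Ddc was at 7.07 times, Maoa at 6.21 and the vesicle transporter gene Slc18a2 at 4.24. Th, the rate-limiting enzyme of catecholamine synthesis, was at 184 CPM and Dbh, which makes noradrenaline, at 297 CPM. Of 12 neuropeptide genes 5 were higher, among them Npy at 802 CPM (ratio 2.80, 2.62 to 3.00), Gal at 169 CPM (3.57), Scg2 (2.25) and Chgb (1.89). In Schwann cell-like nuclei alone Npy was at 594 CPM (524 to 672), closer to the neurons than all other nuclei together. Of 14 stress hormone, nicotinic and adrenergic receptor genes 8 were higher, with Chrm2 at 1195 CPM and 36.3 times the other nuclei (32.1 to 41.2), Chrna7 at 17.4 times and Chrna3 at 3.03, while the mineralocorticoid receptor gene Nr3c2 was at 0.430. Of 10 neurotrophin genes 4 were higher, among them Ret at 2.82 and Ngfr at 1.85, while Ntrk3 was at 0.465. None of 20 chemokine and cytokine genes and none of 20 cytokine receptor genes was higher beyond counting error, counting only genes with at least 20 counts. Ccl25 was at 1.08 (0.864 to 1.34), Il18 at 0.737, Tgfb2 at 0.273, Tgfb3 at 1.16, Lifr at 0.736, Il6st at 0.192, Il1rap at 0.474 and Ifnar2 at 0.291.

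Of 3 cholinergic genes 1 was higher (Ache, 2.31), Slc5a7 was at 1.60 (0.529 to 4.10), Vip at 0.342, and Chat had 3 counts in the neurons and 0 elsewhere. Of 9 members of the immediate early list the only one higher was Gap43 (4.19), a neuronal growth gene and not an immediate early gene, with Nr4a1 at 0.960, Junb at 0.301 and Egr1 at 0.174. Of 4 opioid genes with at least 20 counts 1 was higher, the receptor gene Oprm1 at 9.14 times (6.82 to 12.3), and Oprl1 was at 2.36 (0.893 to 5.64). With fewer counts, the receptor genes Oprd1 (7 and 10 counts, 3.92, 1.27 to 11.4) and Oprk1 (7 and 5 counts, 7.84, 2.14 to 31.3) were higher too, Oprk1 being chosen after its values were seen. Ccl11 had 1 count in these nuclei and 27 in fibroblast-like nuclei, and the enkephalin gene Penk had 1 count. Sub-clusters 0 to 3 held 46, 34, 17 and 11 nuclei, with Npy at 103, 1859, 456 and 368 CPM and Th at 134, 257, 90.1 and 220 CPM. The leading genes of sub-cluster 2 included the adipocyte genes Plin4 and Car3 and the haemoglobin gene Hba-a1.

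The row named Pdyn (ENSMUSG00000027400), a name that stands for the gene of the opioid peptide dynorphin, was lower in the noradrenergic nuclei than in other nuclei. In the ganglia feature list this row stood between the neighbours that the neuropilin gene Nrp2 had in skin. Its counts may therefore be those of Nrp2. The row was at 55.7 CPM in noradrenergic nuclei (88 counts, 44.7 to 68.7) and at 139 CPM in all other nuclei, a ratio of 0.401 (0.319 to 0.497). In sub-clusters 0 to 3 it was at 81.3, 7.23, 55.1 and 106 CPM. A UMI of this row was in 31.5% of noradrenergic nuclei (22.9 to 41.1%) and in 14.6% of Schwann cell-like nuclei. The plan took the latter as free-RNA background, which holds only if the row is Pdyn. The median depths were 10793 and 1319 UMIs. Thinned to 900 UMIs per nucleus, with 106 and 186 nuclei deep enough, the shares were 5.66% (2.11 to 11.9%) and 9.68% (5.84 to 14.9%), with overlapping intervals. For Th, thinned shares were 9.43% and 2.69%, for Dbh 21.7% and 14.0%, and for Npy 26.4% and 23.1%, against unthinned shares of 63.0% and 7.29%, 74.1% and 21.5%, and 81 of 108 nuclei and 36.8%. The thinned intervals of the 2 classes also overlapped for Th, Dbh (14.3 to 30.8% and 9.34 to 19.8%) and Npy (18.3 to 35.9% and 17.3 to 29.85%). Overlap of 2 intervals is not a test of a difference, so it does not settle whether the classes differ. The thinned shares of neurons were higher for Th, Dbh and Npy and lower for the row named Pdyn. That row rested on 6 and 18 nuclei with a UMI after thinning. The row named Nrp2 (ENSMUSG00000025969), a neuropilin gene that endothelial cells express, had no UMI in the 108 noradrenergic or 247 Schwann cell-like nuclei, with upper limits of 3.36% and 1.48% for the shares of nuclei with a UMI. Values of the row named Pdyn, also in the neuropeptide and opioid counts above, are given with the doubt that the file may not pair these 2 names with their counts. If the names were exchanged, these shares describe Nrp2 and not Pdyn.

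**Figure D3:**
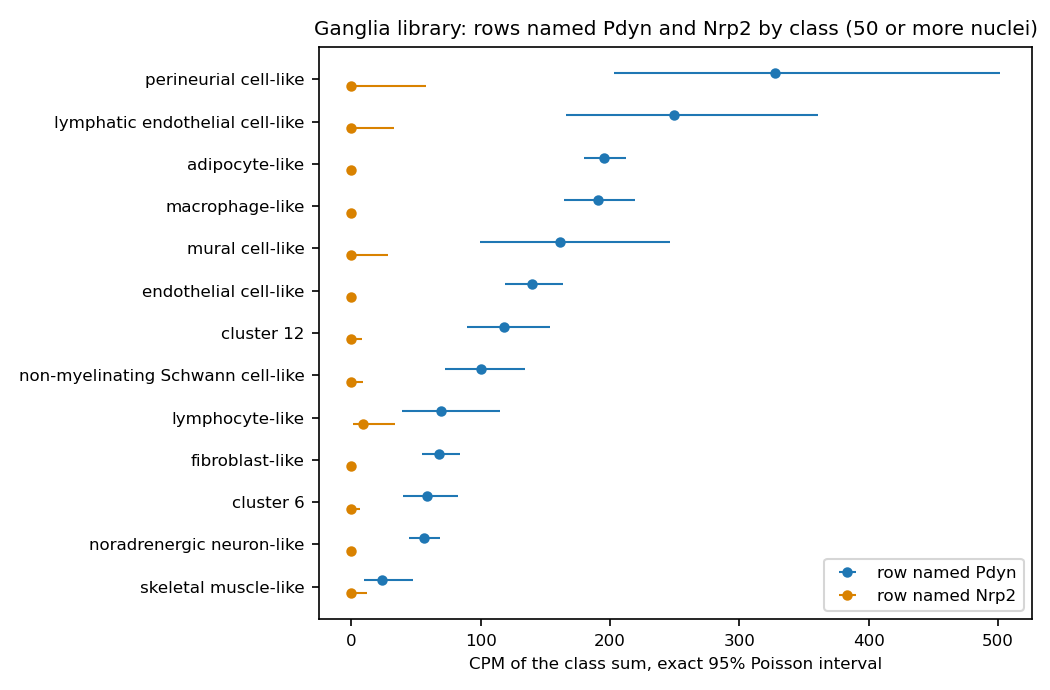
CPM of the class sum (horizontal axis) for the rows named Pdyn and Nrp2 in each ganglia class with at least 50 nuclei (vertical axis), with exact 95% Poisson intervals as bars. The row named Pdyn is at 55.7 CPM in noradrenergic neuron-like nuclei and higher in macrophage-like nuclei (190 CPM), while the row named Nrp2 is at 0 in the classes shown except lymphocyte-like nuclei (2 counts, 9.26 CPM).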

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

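All tests in this part were chosen only after the result was seen. In pooled skin cells 5 transcripts that the comparisons had left aside, as antigen receptor or haemoglobin genes, stood far above their level in the control library. Jchain, the joining chain of secreted antibodies, had 9 counts in the control and 1852 in the RHS library, a ratio of CPM of 214 (112 to 468). Igha, the heavy chain of immunoglobulin A, was at 3.02 and 132 CPM, a ratio of 43.7 (37.4 to 51.4), and Igkc, the kappa light chain, at 14.3 and 226 CPM, a ratio of 15.8 (14.7 to 17.0). Within classes, Igha was higher in 1 of the 3 that measured it, Igkc in 5 of 6 and Jchain in 1 of 1. The haemoglobin genes Hbb-bs and Hba-a1 had ratios of 3.73 (3.43 to 4.05) and 3.61 (3.27 to 3.99). With 1 library per group these differences were not tested between groups.

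Genes that were lower in the RHS library in every class were the first pattern weighed. Of 7432 genes measured in at least 10 of 19 compared skin classes, only those with a median log2 shift of at least 1 were considered. Of these, 64 were lower in every class that measured them and 0 were higher in every class. The median log2 ratio over the 64 was -1.21, a size that this minimum helps to set. Transcripts of the 64 genes had a median GC content of 56.2%, against 48.7% for all genes tested. Over 7429 genes, GC content and the median log2 ratio had a Spearman correlation of -0.238. Subtracting the median of genes of like GC content left 97.6% of the shift, so most genes of like GC content did not share it. The 64 were picked for large shifts that such medians could hardly remove, so a part for GC content was not excluded. For free RNA shared by all classes, the shift in the class where each gene was highest was 1.08 times that in the other classes. Genes not lower in that class could not enter the 64, so this test cannot exclude free RNA. With 1 library per group, a response of all classes to RHS cannot be told apart from these or from a difference between the 2 libraries in handling.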

How the results depend on the processing

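No paired analysis was possible because each group had 1 library. Of 143 ratios of shares over the alternatives, 108 stayed within the interval of the reported value, 33 moved and 2 reversed. Of 580 list medians 503 stayed, 67 moved and 10 reversed, and of 1226 gene ratios 1019 stayed, 180 moved and 27 reversed. Of 11 ganglia shares 5 stayed and 6 moved. Not counted here are scaling by the median ratio, which shifts each class by 1 small constant (log2 -0.185 to 0.11), a minimum of 200 counts, which cannot change a gene ratio, shares without neutrophils, which were too few (1.48% and 1.35%) to move the others, and the marker gate, whose cells were mostly cDC2-like (68.0%), so these do not speak to stability. Where no cause is named below, the cause was not tested.

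At 500 genes per cell the eosinophil share ratio was 0.910 and reversed. In the Prg2 and Ccr3 cluster the log2 ratios of Ccl3 (0.96), Ccl4 (0.32), Cd74 (0.10), Csf1 (0.40), Peg10 (4.65) and Rgs2 (-0.43) reversed, and the medians of chemokines (0.32), inflammatory cytokines (1.00) and oxidative phosphorylation (-0.755) moved, with fewer cells left. In cDC2-like cells Ccl24 (-1.95) and Ddit4 (0.006) reversed, and the cAMP (-0.067) and chemokine (0.18) medians moved. The gamma-delta T inflammatory median (-0.029) reversed. Medians of antigen presentation in alpha-beta T (0.31), of chemokines in Langerhans (0.011) and monocyte-like cells (0.072), and of interferon in Langerhans (-0.085) and monocyte-like cells (-0.55) moved. Share ratios moved for alpha-beta T (1.76), cDC2 (0.80035), fibroblast (1.64), gamma-delta T (0.314) and monocyte-like cells (1.43).

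With doublets kept, Ccl24 in cDC2-like cells (-1.775) and Cdk1 in monocyte-like cells (-0.17) reversed, the chemokine medians of cDC2-like (0.21) and monocyte-like cells (0.045) moved, and share ratios were 2.23 (alpha-beta T), 0.849 (cDC2) and 1.82 (fibroblast). At resolution 0.5 share ratios were 1.69 (alpha-beta T), 0.877 (cDC2) and 1.88 (fibroblast), and at 2.0 they were 0.794 (cDC2), 1.87 (fibroblast), 1.74 (macrophage) and 1.45 (monocyte). At most 10% mitochondrial UMIs gave 1.65 (alpha-beta T), 0.865 (cDC2), 1.77 (fibroblast), 0.390 (keratinocyte) and 1.81 (macrophage). Separate clustering gave 0.736 (Langerhans), 1.31 (alpha-beta T), 0.824 (cDC1), 1.38 (fibroblast) and 2.47 (macrophage). Clustering without the fixed marker genes, chosen after seeing the data, reversed the fibroblast ratio (0.583). Among clusters with Ptprc, also chosen after seeing the data, the ratios were 0.857 (Langerhans), 2.09 (alpha-beta T), 0.715 (basophil), 0.890 (cDC2), 0.322 (gamma-delta T), 1.71 (macrophage), 1.11 (monocyte) and 0.811 (regulatory T), with fewer cells in the denominator.

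With at least 100 counts the gamma-delta T inflammatory (-0.35) and alpha-beta T type 2 (0.42) medians reversed, and interferon in Langerhans (-0.19) and monocyte-like cells (-0.548) and lipid mediators in alpha-beta T cells (0.655) moved, with fewer genes measured. Subtracting 5% free RNA reversed the keratinocyte Fc receptor (-0.57) and chemokine (-0.36) and gamma-delta T inflammatory (-0.18) medians, and moved chemokines in alpha-beta T (0.067) and monocyte-like cells (0.002) and immediate early genes in alpha-beta T cells (-0.31).

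Relative to the other classes, a setting chosen after seeing the data, these log2 ratios reversed: B2m in mast cells (-0.011), Ccl6 in the Prg2 and Ccr3 cluster (-0.31) and monocytes (-0.25), Ccl9 in that cluster (-0.48), Ear2 in cDC2 (-0.57) and keratinocytes (-0.009), H2-DMa in alpha-beta T cells (0.40) and macrophages (0.056), Hspa1a in Langerhans cells (-0.14), Il4ra in macrophages (0.19), Il6 in basophils (-0.18), Mt2 in macrophages (0.45) and monocytes (0.27), Ppp1ca in Langerhans cells (0.205), Selplg in alpha-beta T cells (0.059), Thbs1 in cDC2 (-0.032) and Tpi1 in monocytes (-0.082). Reversed medians were chemokines in Langerhans (-0.18) and monocyte-like cells (-0.20), glucocorticoid genes in macrophages (0.045) and type 2 cytokines in alpha-beta T cells (0.45). Moved medians were antigen presentation in the Prg2 and Ccr3 cluster (-0.38) and alpha-beta T cells (0.31), chemokines in that cluster (-0.415), alpha-beta T (0.24), cDC2 (0.20) and keratinocyte-like cells (0.26), eosinophil genes in cDC2 (0), glucocorticoid (-0.039) and glycolysis genes (-0.017) in monocytes, immediate early genes in Langerhans cells (0.095), and interferon in Langerhans (-0.07), macrophage (-0.47) and monocyte-like cells (-0.38).

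The share of noradrenergic nuclei was 4.95% at 1000 genes per nucleus and 3.39% at 1% mitochondrial UMIs. The share of them with a UMI of the row named Pdyn was 22.7% at 1% mitochondrial UMIs, 18.5% at 2 UMIs, 5.66% thinned and 0% for the row named Nrp2 (chosen after seeing the data). Depth limits most the Prg2 and Ccr3 cluster, with 52573 and 68474 UMIs. Some alternatives gave no value for a class that lost its name or for a ratio with 3 counts or fewer left in both libraries.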

Other observations

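The tests on the rows named Pdyn and Nrp2 and on a response to RHS were chosen only after the result was seen, while the test of free RNA for the chemokines was written before its result. NK cell-like cells had higher proliferation genes in the RHS library, with 10 of 10 measured members higher (median log2 ratio 0.72), Birc5 at 2.27 (10 and 19 counts, 1.01 to 5.47) and Mki67, a gene of cycling cells, at 2.14 (29 and 52 counts, 1.34 to 3.50). Of 10 chemokine list genes that NK cell-like cells held at under 0.2 of the level of other cells 8 were higher, with log2 ratios from -0.742 for Ccl3 to 4.94 for Cxcl3. Members of the antigen presentation list, which mixes class I and class II genes, were mostly higher in neutrophil-like, mast cell-like and fibroblast-like cells. In neutrophil-like cells 11 of 11 antigen presentation genes were higher (median 1.11), with H2-Aa at 3.99 (3.47 to 4.61), H2-Ab1 at 3.58 (3.08 to 4.19) and B2m at 1.01. In mast cell-like cells 8 of 9 were higher (median 0.70), with H2-Eb1 at 4.90 (3.50 to 6.97). In fibroblast-like cells 8 of 8 were higher (median 2.92), with Cd74 at 13.03 (19 and 487 counts, 8.25 to 21.8), beside genes of other cells such as Ccl6 (log2 ratio 5.51) and Ccl3 (3.99). No test separated expression from doublets or free RNA in these 4 classes.

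B cell-like cells had no cluster of their own in the clustering reported. Cluster 16, named cDC1-like, had Igkc as its leading gene and B cell as its second-best class, so its values include such cells. A B cell-like cluster appeared under 6 other settings, with 46 control and 28 RHS cells at 500 genes per cell and 54 and 31 without the fixed marker genes. The skin libraries held almost no Xist (1 and 0 UMIs) and much Ddx3y (6935 and 5951 UMIs), while the pooled ganglia library held both (3998 and 1223 UMIs).

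The ganglia row named Pdyn had UMIs in nearly every class, and the row named Nrp2 held 2 UMIs in all. A candidate explanation is that these 2 names were exchanged in the ganglia feature list. The upper limit of the row named Nrp2 was 1.27% of the skin level of Nrp2 in macrophage-like and 1.08% in endothelial nuclei, while the row named Pdyn reached 67.0% and 45.2% of that level, and each name stood between the neighbours that the other had in skin. Free RNA from noradrenergic neurons was argued against, since the row named Pdyn was at 0.401 of its level in all other nuclei there. The design gives no biological partner group, so no biological explanation was tested.

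Chemokines were higher in the RHS library in many skin classes, and over all cells 18 of 23 members were higher (median log2 ratio 0.54). Free RNA from chemokine-producing cells may contribute. The test took 12 classes, chosen because their chemokine list was high in the RHS library against random lists. In them, members at under 0.2 of the level of other cells had a median of 0.84 (89 pairs of gene and class). Members at or above the full level of other cells had a median of 0.12 (58 pairs). Classes without a high list, such as macrophage-like cells, were left out, so the choice of classes may set part of this contrast. Free RNA also cannot be told apart here from a response of the chemokine-producing classes to RHS, for which there was 1 library per group.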
